A study of Homo sapiens with 30 samples.

How the data were processed

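The series holds 30 Affymetrix arrays, 10 of epidermis captured by laser from normal skin, 10 of sorted keratinocytes and 10 of cultured normal human epidermal keratinocytes, each sample assigned to its group by its own label. Per the labels, RNA was purified with a column kit and labelled with biotin. The authors deposited 1 log2 value per probe set and array, made with GCRMA, which corrects background by probe sequence, normalizes across arrays and summarises each probe set, per the submitters' processing notes; the log2 scale was read from the values. The version of GCRMA, the software and whether all arrays were processed together are not given in the sources used here. GCRMA sets a shared floor, 2.26 here, so differences of weakly expressed genes are compressed or depend on that floor. Arrays have no read depth, and their number limits the precision. The smallest root mean square difference between any 2 arrays was 0.411 log2 units, so no array was counted as a duplicate.

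Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and were not named, 11777 were not listed there, which includes 62 controls. Symbols were updated through Entrez gene identifiers against RefSeq's list of genes, which matched 40978 probes and missed 54; no coordinates are given because the sources name no genome build. Sex-linked transcripts (35 genes) were left out. Each gene was represented by its probe with the highest mean over all arrays, which can differ from its other probes: among 4835 genes with several detected probes, 297, 330 and 97 had probes changing at least 2-fold in opposite directions in sorted against captured, cultured against captured and sorted against cultured samples. Genes above 4 log2 units on at least 10 arrays were tested, 10871 of 19740.

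All 30 arrays entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3, data.table version 1.17.8; lmFit and eBayes), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Adjusted p-values of single genes in the text are from this model. Gene lists (35 lists, fixed before the data were examined, of which 34 had a tested member) were tested with camera at a preset correlation of 0.01, adjusted over 102 tests, and again with an estimated correlation and with fry. They cover keratinocyte differentiation, wound, stress, immune and metabolic genes and markers of other cell types. Members were counted with p adjusted over all genes and over the list alone. CCL20 and the array controls were tested by two-sided permutation tests with 100000 resamples in scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9. Overlaps of calls against the shared captured arrays were set beside 20 simulated sets of unchanged groups, the overlap of independent lists, and 20 splits of the captured arrays, and calls were recounted over 100 splits of the samples.

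Named genes followed a rule fixed before the data were examined: CCL20; in each comparison the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap and whose higher group had a mean of at least 6; up to 4 called members per described list; and CXCL8. Leukocyte and hair follicle genes in the closing section were named outside the rule after their values were seen. Alternatives were other low-value filters, quantile normalization, median centring, other probe rules, trended and robust moderation, treat, array weights, 2-group fits, the replicate number as a block and each array left out, with 3 settings on RNA quality added after the data were seen. The model was tested on simulated data with the spread of the 10871 tested genes and 200 genes changed by 3, 4 or 8-fold. It recovered 82.1%, 95.5% and 100% of these in sorted against captured samples, 88.1%, 95.5% and 98.5% in cultured against captured and 91.0%, 94.0% and 98.5% in sorted against cultured, and called 4, 4 and 1 unchanged genes. A list shifted in the simulation was found in each comparison, with 1, 0 and 0 of 33 other lists called. The simulated genes varied independently and had no floor, whereas estimated correlations within the real lists reached 0.69. The simulation thus does not show how the calls or camera perform on correlated genes.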

Results

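Gene expression was profiled on 30 Affymetrix arrays of human keratinocytes, the main cells of the epidermis, in 3 groups of 10 arrays. The first group was epidermis cut from sections of normal skin by laser capture microdissection (LCM), which takes the cells without dissociating the tissue. The second was keratinocytes obtained by cell sorting, and the third was normal human epidermal keratinocytes grown in culture. The series asks how keratinocytes respond when the tissue is taken apart, with captured epidermis and cultured cells as the references. Values were log2 probe intensities with a shared lowest value of 2.26 on every array, and 10871 of 19740 genes were tested. The median correlation between arrays was 0.932 within captured epidermis, 0.924 within sorted cells and 0.950 within cultured cells, against 0.716, 0.685 and 0.744 between the groups. Centring each array on the median of the tested genes moved the median of all genes by 0.13 log2 units for sorted cells against captured epidermis, -0.28 for cultured cells against captured epidermis and 0.41 for sorted against cultured cells, and quantile normalization moved the last by 0.11. The first 2 principal components held 40.7% and 31.2% of the variance and separated the 3 groups. The labels say neither whether the arrays of a group came from separate donors or cultures, nor whether captured regions shared a donor, so p-values measure only the spread between these samples, which may be technical and may make them too small. They also give neither the gate of the sort nor which cultures, if any, received the IL-17 and TNF named in the shared growth protocol.

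**Figure D1:**
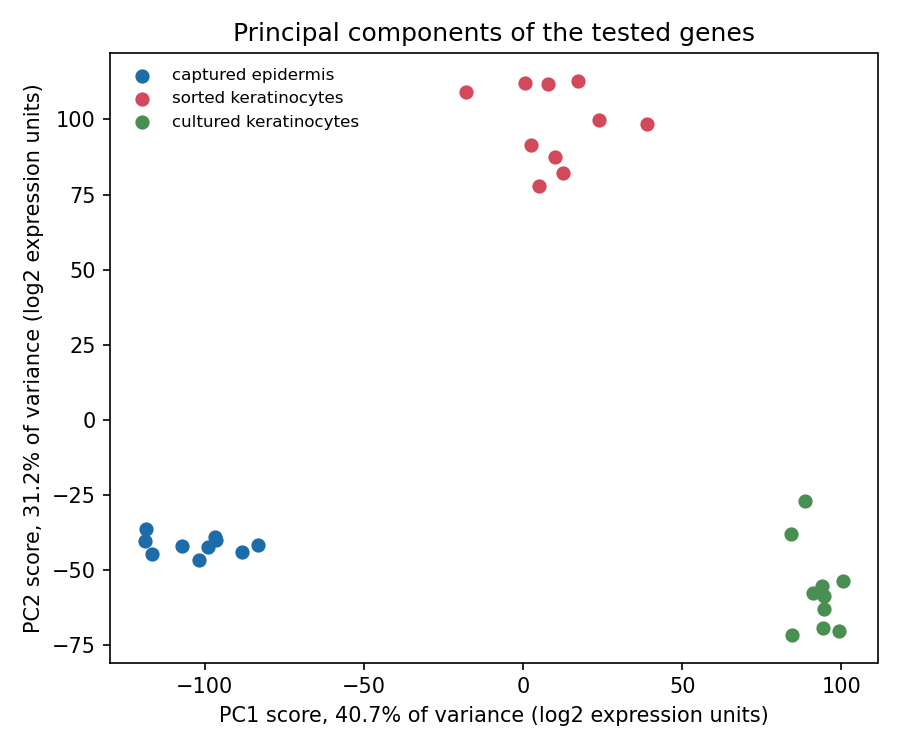
Scores of the 30 arrays on the first 2 principal components of the tested genes (arbitrary units of log2 expression), 1 point per array, coloured by group. The 10 arrays of each group lie together and apart from the other groups.

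The gap between 3 prime and 5 prime control probes differed between the groups. Such gaps can arise from RNA integrity or from amplification, which were not told apart here. For ACTB, the beta-actin control gene, the probe at the 3 prime end exceeded the probe at the 5 prime end by 9.53 ± 0.84 log2 units (SD, n = 10) in captured epidermis, 5.37 ± 0.42 in sorted cells and 5.56 ± 0.85 in cultured cells. The corresponding gaps for GAPDH, a glycolytic control gene, were 4.92 ± 1.05, 3.56 ± 0.45 and 2.49 ± 0.69. Both gaps were larger in captured epidermis than in sorted cells (permutation test, two-sided, Benjamini-Hochberg adjusted over 21 tests, p = 3.50e-05 for ACTB and 0.00165 for GAPDH). They were also larger there than in cultured cells (p = 3.50e-05 for each gene). Between sorted and cultured cells the ACTB gap differed by -0.19 (adjusted p = 0.543) and the GAPDH gap by 1.07 (adjusted p = 0.000646). The bacterial spike-in bioB, added in fixed amounts, was at 9.04 ± 0.42, 8.93 ± 0.36 and 7.64 ± 0.17 in captured, sorted and cultured samples, and 18S ribosomal RNA at 13.72 ± 0.30, 13.31 ± 0.24 and 12.15 ± 0.69. Both were lower in the cultured samples than in captured epidermis (adjusted p = 3.50e-05 for each). Sorted minus captured differences were -0.41 for 18S, -0.51 for the spike-in bioD and -0.41 for cre (permutation test, adjusted p = 0.00481, 0.00368 and 0.00165). For bioB and bioC they were -0.11 and -0.23 (permutation test, adjusted p = 0.543 and 0.210). No label gives a processing batch, so batch and group cannot be told apart.

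**Figure D2:**
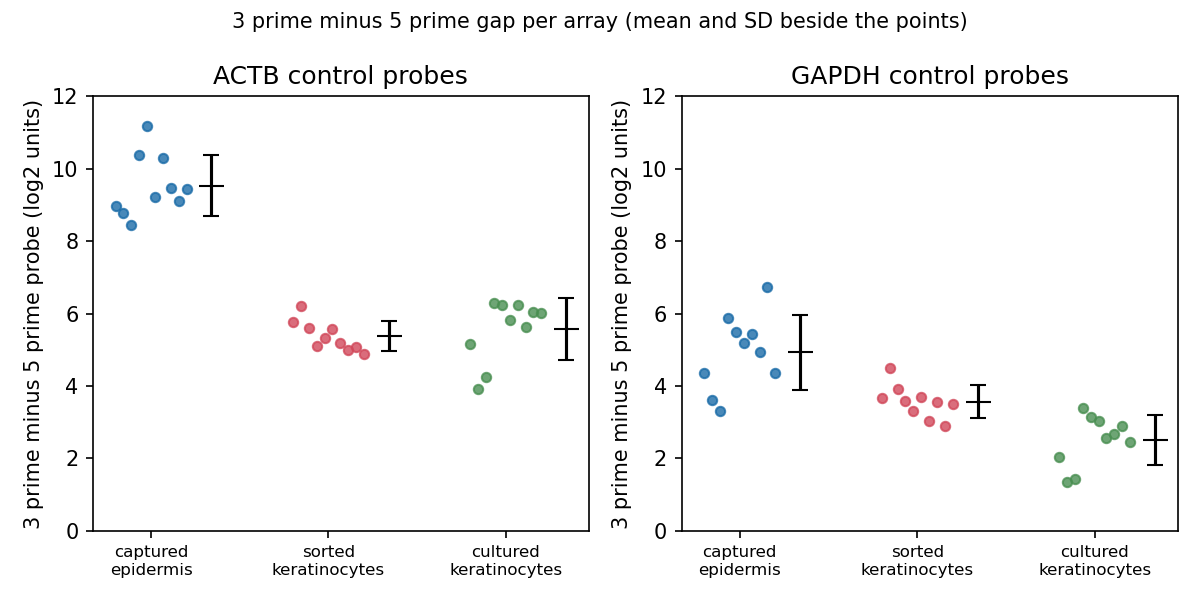
Difference between the 3 prime and 5 prime control probes of ACTB and GAPDH (log2 units) on each of the 30 arrays, with the mean and SD of each group. The ACTB gap lies between 8.45 and 11.18 on the captured arrays and at or below 6.29 on the others.

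CCL20, the chemokine that attracts cells carrying the receptor CCR6 and that the title of the series names, was near the floor of the array in captured epidermis and high in sorted cells. Its level was 2.44 ± 0.31 log2 units (SD, n = 10) in captured epidermis, 13.44 ± 0.46 in sorted cells and 4.76 ± 1.70 in cultured cells. The difference between sorted cells and captured epidermis was 10.999 ± 0.44 log2 units (SE), a 2047-fold change (adjusted p = 1.96e-19, limma with Benjamini-Hochberg). Cultured cells exceeded captured epidermis by 2.32 ± 0.44 and sorted cells exceeded cultured cells by 8.68 ± 0.44 (adjusted p = 2.68e-05 and 1.20e-16, limma with Benjamini-Hochberg). A permutation test gave adjusted p = 3.00e-05, 0.000220 and 3.00e-05 for the 3 comparisons, where 2e-05 is the smallest unadjusted p that 100000 permutations can give. A fold against a group near the floor depends on where the floor lies, here and for every gene below with a level near 2.26. With the array's mean 3 prime minus 5 prime gap as a covariate, a setting added after the data were seen, the difference between cultured cells and captured epidermis was 1.60 ± 0.98 and no longer passed (adjusted p = 0.224, range 1.90e-06 to 0.224 over its settings, limma with Benjamini-Hochberg), because its standard error grew and its size shrank.

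**Figure D3:**
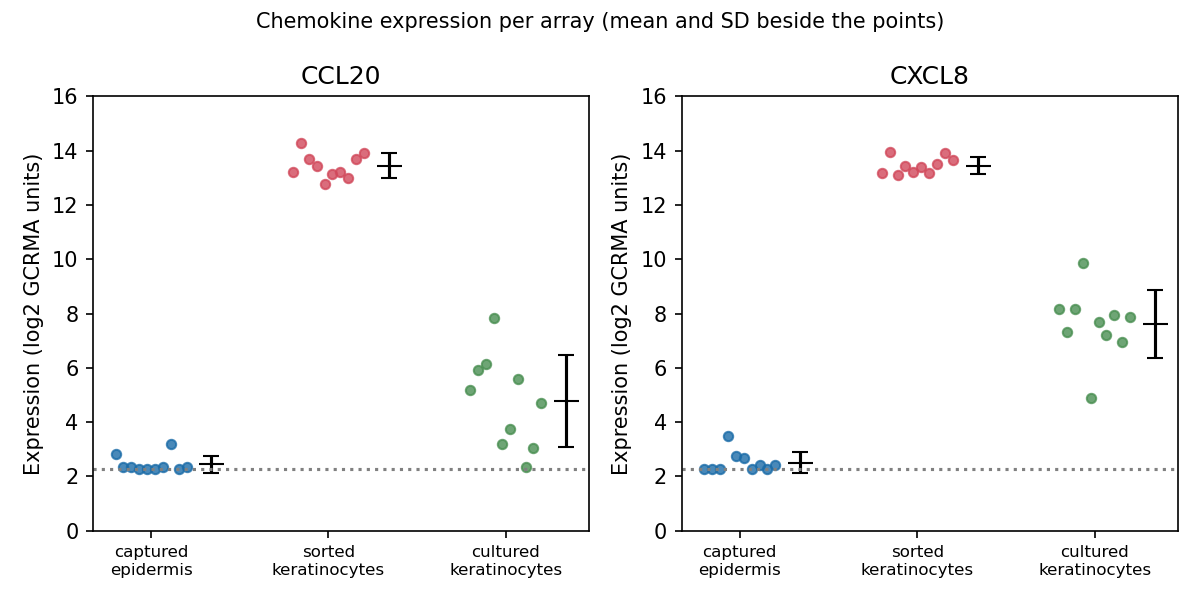
Log2 expression of the chemokine genes CCL20 and CXCL8 on each of the 30 arrays, with the mean and SD of each group and a dotted line at the lowest value of the arrays. Both genes lie near that line in captured epidermis and highest in sorted cells.

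Sorted keratinocytes were compared with captured epidermis to ask what dissociation and sorting change. IL1RL1, the receptor for the alarmin IL33, rose 2702-fold (11.40 ± 0.41 log2 units, SE, n = 10 per group), and the neutrophil-attracting chemokine CXCL8 rose 1986-fold (10.96 ± 0.33). The collagenase MMP1 and the stromelysin MMP3 rose by 10.84 ± 0.46 and 10.44 ± 0.63, and PLAUR, the urokinase receptor, by 9.31 ± 0.30. The largest decreases were in FLG2, LORICRIN and FLG, proteins of the outermost epidermis: FLG2 fell by 12.16 log2 units, from 15.47 ± 0.20 to 3.31 ± 1.26, LORICRIN fell by 9.39 and FLG, filaggrin, fell by 8.69. PHLDA1 and GPRC5A were among the other large increases, at 9.95 and 9.47, and AZGP1, LCE2B, ARG1, LAMB4 and HLA-DQB2 among the other large decreases, at -8.11, -7.56, -7.14, -6.99 and -6.49. Each of these genes had an adjusted p of at most 8.79e-10 (limma with Benjamini-Hochberg).

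Stress and injury programmes rose in sorted cells. Of the immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 24 of 28 rose and none fell, among them FOSL1 (log2 difference 9.002), ATF3 (6.48) and NR4A2 (6.20), at camera adjusted p = 2.08e-15 (adjusted p = 0.00816 with an estimated correlation). Of the NF-kappaB targets 14 of 15 rose, with CD83 (5.52), NFKBIE (5.37) and IRF1 (4.85), at camera adjusted p = 4.73e-08 (adjusted p = 0.0123 with an estimated correlation). Of the chemokines 6 of 8 rose and 2 fell, with CXCL2 and CXCL3 at 8.23 and 7.62 beside CCL20 and CXCL8 (camera adjusted p = 0.000637, adjusted p = 0.0476 with an estimated correlation). The list of wound keratins, migration genes and proteases rose in 14 of 16 members (camera adjusted p = 2.04e-08, adjusted p = 0.00816 with an estimated correlation). The 5 prime end of control transcripts was also higher in sorted cells relative to captured epidermis, as given above, beside all of these groups.

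Other stress lists passed by camera with the preset correlation and not with an estimated one. These were the unfolded protein response with 13 of 14 members, led by PPP1R15A (6.13) and CHAC1 (4.92), at camera adjusted p = 2.09e-08 (adjusted p = 0.0825 with an estimated correlation). Among them were also the heat shock proteins with 10 of 13, led by HSPA6 (6.56) and HSPH1 (3.92), at camera adjusted p = 9.72e-07 (adjusted p = 0.185 with an estimated correlation). Ligands and feedback regulators of the EGF receptor rose in 9 of 12 members and fell in 1, with HBEGF (7.97) and BTC (-6.19), at camera adjusted p = 4.75e-05 (adjusted p = 0.103 with an estimated correlation). Glycolysis and hypoxia genes rose in 12 of 18, with adrenomedullin, ADM (4.82), at camera adjusted p = 3.81e-05 (adjusted p = 0.293 with an estimated correlation). Antioxidant targets of NRF2 rose in 7 of 11, with TXNRD1 (5.66) and GCLM (4.45), at camera adjusted p = 0.00763 (adjusted p = 0.293 with an estimated correlation). Cytokines rose in 10 of 19 and fell in 4, with IL37 (-5.91), TSLP (5.27) and IL36G (5.10), at camera adjusted p = 0.0138 (adjusted p = 0.175 with an estimated correlation). Antimicrobial peptides and alarmins rose in 6 of 10 and fell in 1, with S100A9 (7.57), S100A8 (7.07) and S100A7 (5.86), at camera adjusted p = 0.0321 (adjusted p = 0.438 with an estimated correlation). Without captured replicate 7, S100A8 was higher by 7.75 and S100A7 by 6.61.

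Differentiation, division and Langerhans cell genes fell in sorted cells. The share of cell types and layers in each group was not measured, here or below. Such decreases, with those of FLG2, LORICRIN and FLG above, can therefore reflect fewer such cells as well as lower expression. Suprabasal differentiation genes fell in 10 of 14 members and rose in none, with the desmosomal cadherins DSC1 (-4.02) and DSG1 (-3.56), at camera adjusted p = 0.00222 (adjusted p = 0.435 with an estimated correlation). Cell cycle genes fell in 17 of 23, with TOP2A (-4.31) and RRM2 (-4.22), at camera adjusted p = 0.0116 (adjusted p = 0.708 with an estimated correlation). All 12 tested markers of Langerhans cells, the dendritic cells of the epidermis, and MHC class II fell, with HLA-DPA1 (-6.26) and CD1A (-5.77), at camera adjusted p = 2.97e-08 (adjusted p = 0.0825 with an estimated correlation). In the list of the cornified envelope and granular layer 11 of 19 fell and 6 rose, 12 and 6 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0889). It passed with no low-value filter, centred arrays or the gap covariate (camera adjusted p = 0.0117 to 0.0476, range 0.0117 to 0.761 over its settings), settings in which its median was -4.54 to -1.65 instead of -2.09. For the other lists in these paragraphs the counts adjusted over the list alone were the same as over all genes.

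In all, 2187 genes were at least 2-fold higher and 2773 at least 2-fold lower in sorted cells (limma with Benjamini-Hochberg), and 15 of 34 lists shifted by camera with the preset correlation, of which 4 held with an estimated correlation. Tested against a 2-fold change (treat), 1313 were higher and 1494 lower. The cytokine list did not pass with a stricter low-value filter, probe means or without the x_at and s_at probe sets (camera adjusted p = 0.315, 0.104 and 0.0553). Nor did it pass without any 1 of sorted replicates 1, 3, 4, 5, 6, 7, 8, 9 or 10 (camera adjusted p = 0.0571 to 0.0784, range 0.00516 to 0.315 over its settings). Without an array, members could also leave the list through the filter, so these losses do not show dependence on single replicates. The chemokine list did not pass without the x_at and s_at probe sets (camera adjusted p = 0.0832, range 1.29e-05 to 0.0832 over its settings).

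Cultured keratinocytes were compared with captured epidermis as the second reference of the series. The protease inhibitor SERPINE2 rose 781-fold (9.61 ± 0.38 log2 units, SE, n = 10 per group), the matrix protein THBS1, thrombospondin, by 9.10 ± 0.39, DKK1, a secreted Wnt inhibitor, by 9.37 ± 0.53, and KRT18, a keratin of simple epithelia, by 8.97 ± 0.48. KRT2, a keratin of the upper epidermis, fell by 12.17 log2 units, from 14.72 ± 0.19 to 2.55 ± 0.27. Other large increases were in PHLDA1, AMIGO2, SPINK6 and FST, at 9.57, 9.26, 9.02 and 8.99, and other large decreases in CRIP1, DAPL1, TNFRSF19, ID4, GATM, HLA-DPA1 and TPPP3, at -9.14, -9.03, -8.91, -8.67, -8.55, -8.31 and -8.24. Each of these genes had an adjusted p of at most 1.66e-10 (limma with Benjamini-Hochberg).

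Wound and proliferation genes rose in culture and differentiation genes fell. The list of wound keratins, migration genes and proteases rose in 14 of 16 members, with FN1, fibronectin, at 8.55 (camera adjusted p = 4.60e-07, adjusted p = 0.0148 with an estimated correlation). Cell cycle genes rose in 21 of 23, with CCNB1 (4.65), TPX2 (4.64) and AURKA (4.51), at camera adjusted p = 0.00283 (adjusted p = 0.701 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 13 and fell in none, with STARD4 (6.05) and INSIG1 (4.05), at camera adjusted p = 0.000720 (adjusted p = 0.293 with an estimated correlation). EGF receptor ligands and feedback regulators rose in 11 of 12 and fell in 1, with DUSP4 (6.84), at camera adjusted p = 0.00201 (adjusted p = 0.253 with an estimated correlation). The unfolded protein response rose in 10 of 14, with DDIT4 (4.11) and TRIB3 (3.61), at camera adjusted p = 0.00722 (adjusted p = 0.435 with an estimated correlation). Basal keratinocyte genes rose in 6 of 11 and fell in 1, with LAMB3 (6.49) and CDH3 (5.66), at camera adjusted p = 0.0143 (adjusted p = 0.293 with an estimated correlation). Suprabasal differentiation genes fell in 13 of 14, with KRT1 (-6.16) and CALML5 (-5.45), at camera adjusted p = 2.48e-08 (adjusted p = 0.110 with an estimated correlation). Cornified envelope and granular layer genes fell in 11 of 19 and rose in 6, with LORICRIN (-7.62), FLG2 (-6.10) and SPRR1A (5.32), at camera adjusted p = 0.0283 (adjusted p = 0.704 with an estimated correlation). All 12 Langerhans cell and MHC class II markers fell (camera adjusted p = 1.71e-10, adjusted p = 0.0432 with an estimated correlation). Cultured replicate 5 stood apart in the cell cycle and cholesterol lists: TOP2A was at 3.47 on cultured replicate 5 against 9.74 to 11.35 on the other 9 cultured arrays, and SQLE at 11.45 on cultured replicate 5 against 12.28 to 13.07 on the other 9 cultured arrays. Without that array the median over the cell cycle list was 2.37 instead of 2.02 and over the cholesterol list 2.60 instead of 2.43, and 3141 genes were higher and 2054 lower.

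The inflammatory lists went both ways in culture and did not pass as lists. Chemokines rose in 5 of 8 members and fell in 2 (camera adjusted p = 0.465), with CXCL8 at 5.10 ± 0.33 and CCL27, the skin chemokine for homing T cells, at -8.16 ± 0.27 (adjusted p = 2.55e-14 and 3.12e-21, limma with Benjamini-Hochberg). With the probe of the highest mean in captured epidermis, CXCL8 differed by 0.08 and did not pass. Immediate early genes rose in 8 of 28 and fell in 8 (camera adjusted p = 0.879), NF-kappaB targets in 7 and 3 of 15 (camera adjusted p = 0.879), and cytokines in 5 and 5 of 19, with IL1A (8.54) and IL1B (6.74), at camera adjusted p = 0.808. Adjusted over the list alone, the counts of every list in these paragraphs on cultured cells were the same.

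In cultured cells 3188 genes were at least 2-fold higher and 2068 lower than in captured epidermis (limma with Benjamini-Hochberg), 60.7% of them higher, and with arrays centred on the median 2516 were higher and 2594 lower, 49.2% higher. Of 34 lists 13 shifted by camera with the preset correlation and 2 with an estimated correlation. Centring ended the call of the cornified envelope list (camera adjusted p = 0.0817), as did leaving out cultured replicate 10 (0.0513) or the x_at and s_at probe sets (0.0553, range 0.00123 to 0.704 over its settings). Leaving out these probe sets also ended the calls of the unfolded protein response (0.0559, range 9.74e-05 to 0.435 over its settings) and basal lists (0.157, range 1.48e-05 to 0.293 over its settings). Treat left 1855 genes higher and 1206 lower, and the 3 prime minus 5 prime gap as a covariate 1390 higher and 1878 lower. With that covariate the cell cycle list no longer passed (median 0.32, camera adjusted p = 0.424, range 8.38e-07 to 0.701 over its settings), nor did CCNB1, TPX2 and AURKA, at 2.28, 1.57 and 0.63.

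Sorted and cultured keratinocytes, whose ACTB gaps were similar and whose GAPDH gaps differed by 1.07, were compared directly to set the response to dissociation against cells adapted to culture. HSPA6, a stress-induced heat shock protein, was 932-fold higher in sorted cells (9.86 ± 0.26 log2 units, SE, n = 10 per group), IL1RL1 859-fold (9.75 ± 0.41) and MMP3 564-fold (9.14 ± 0.63). MMP3 was at 10.25 on cultured replicate 5 against 2.53 to 3.90 on the other 9 cultured arrays, and without that array it was 923-fold higher (9.85 ± 0.33). KRTAP3-2, a keratin-associated protein of the hair shaft, PDE4B, a phosphodiesterase that degrades cyclic AMP, KRT2 and the immediate early gene FOSB were higher by 9.13, 9.05, 9.04 and 8.02. Among the genes lower in sorted cells, the log2 difference was -8.60 ± 0.41 for FN1, -8.22 ± 0.63 for SCD, the stearoyl-CoA desaturase, -7.73 for MFAP5, a microfibril protein, and, for UPK1B, STARD4, TP53I3, HTRA1 and FBN2, -7.81, -7.07, -6.85, -6.79 and -6.60. Each of these genes had an adjusted p of at most 1.99e-12 (limma with Benjamini-Hochberg).

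Of the immediate early genes 23 of 28 were higher in sorted than in cultured cells and none lower, with NR4A2 (log2 difference 6.75), FOS (6.07) and ATF3 (6.02), at camera adjusted p = 8.14e-16 (adjusted p = 0.00816 with an estimated correlation). NF-kappaB targets were higher in 13 of 15, with IRF1 (5.12), CD83 (4.50) and NFKBIZ (3.89), at camera adjusted p = 2.04e-08 (adjusted p = 0.00959 with an estimated correlation), and lower in 0, or 1 adjusted over the list alone. Chemokines were higher in 7 of 8, with CXCL8 (5.85), CXCL3 (5.73) and CCL27 (5.59), at camera adjusted p = 1.22e-06 (adjusted p = 0.00816 with an estimated correlation). These 7 include the 2 chemokines, CCL27 among them, that were lower in sorted cells than in captured epidermis. Cytokines were higher in 12 of 19 and lower in 4, with IL1B (-6.15), IL36G (5.23) and IL33 (4.55), at camera adjusted p = 0.00910 (adjusted p = 0.149 with an estimated correlation). Heat shock proteins were higher in 6 of 13, with DNAJB4 (2.89) and HSPA1L (2.31), at camera adjusted p = 0.00763 (adjusted p = 0.489 with an estimated correlation). The unfolded protein response was higher in 9 of 14, with PPP1R15A (5.12) and DDIT3 (3.30), at camera adjusted p = 0.000375 (adjusted p = 0.293 with an estimated correlation).

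Suprabasal differentiation genes were higher in sorted cells in 10 of 14 members and lower in 1, with KRT1 (4.83) and KRT10 (2.43), at camera adjusted p = 0.000494 (adjusted p = 0.375 with an estimated correlation). Cell cycle genes were lower in 22 of 23, with TYMS (-6.30), RRM2 (-6.11) and BUB1B (-5.98), at camera adjusted p = 4.60e-07 (adjusted p = 0.424 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 13, with FDPS (-3.77) and SQLE (-3.59), at camera adjusted p = 0.000665 (adjusted p = 0.293 with an estimated correlation). In these lists cultured replicate 5 stood apart, as above: RRM2 was at 8.01 on cultured replicate 5 against 11.34 to 12.81 on the other 9 cultured arrays, and without that array the medians over the 2 lists were -5.31 and -2.11 instead of -4.76 and -2.02, BUB1B was at -6.59, with 1742 genes higher and 3294 lower. Basal keratinocyte genes were lower in 5 of 11, with the integrin ITGB4 (-4.65) and ITGA3 (-3.67), at camera adjusted p = 0.0120 (adjusted p = 0.293 with an estimated correlation). The wound list, higher in both groups than in captured epidermis, was higher in sorted cells in 4 and lower in 5 of 16 members (camera adjusted p = 0.929). Apart from the NF-kappaB targets, the counts adjusted over the list alone were the same in these paragraphs on sorted against cultured cells.

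Between sorted and cultured cells 1733 genes were at least 2-fold higher and 3306 lower in sorted cells (limma with Benjamini-Hochberg), 34.4% higher, against 2510 and 2328, or 51.9% higher, with arrays centred on the median. Of 34 lists 14 shifted by camera with the preset correlation and 3 with an estimated correlation. Treat left 958 higher and 1870 lower, and the calls of heat shock proteins and basal genes were lost without the x_at and s_at probe sets (camera adjusted p = 0.0786, range 0.00343 to 0.489 over its settings, and 0.0810, range 0.000468 to 0.293 over its settings). The call of the cytokine list was lost with a stricter filter (camera adjusted p = 0.151, range 0.00681 to 0.151 over its settings) and without any 1 of sorted replicates 1, 3, 4, 5, 6, 7, 8 or 9 (0.0542 to 0.0640). Here too members could leave the list through the filter. The lower spike-in and 18S signals and the smaller GAPDH gap of the cultured samples stand beside every group in this comparison.

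**Figure D4:**
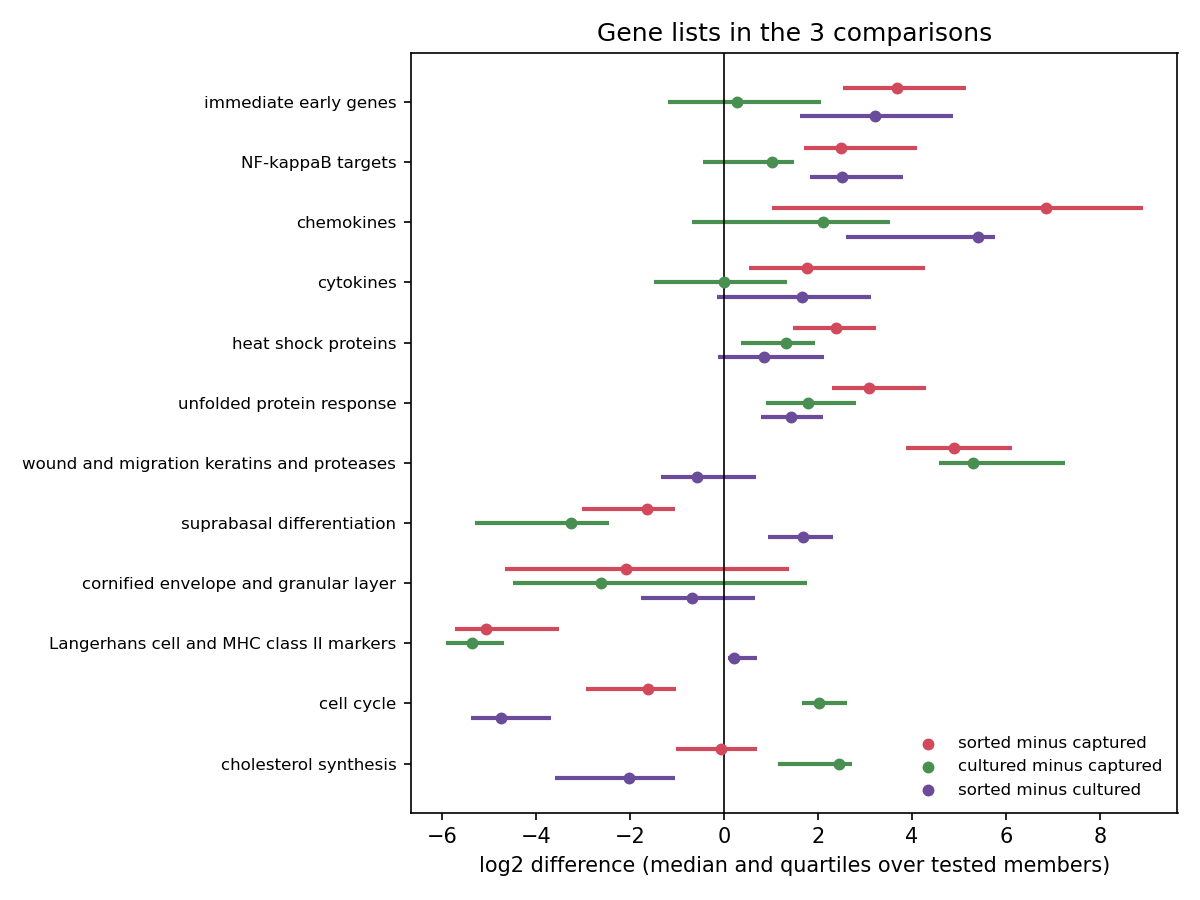
Median log2 difference over the tested members of 12 gene lists in each of the 3 comparisons, with lines from the first to the third quartile of the members. The immediate early, NF-kappaB and chemokine lists lie to the right of 0 for sorted cells against either reference.

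The calls of sorted and of cultured cells against captured epidermis were then set side by side. Wound genes were higher in both groups in 13 of 16 members, the unfolded protein response in 10 of 14 and glycolysis and hypoxia genes in 10 of 18. S100A8, an alarmin of stressed epidermis, was at 6.999 ± 2.77 in captured, 14.07 ± 0.98 in sorted and 13.39 ± 0.84 in cultured samples. Suprabasal genes were lower in both in 10 of 14, the cornified envelope list in 11 of 19 and Langerhans cell markers in 12 of 12. Over all genes 1323 were higher and 1260 lower in both groups, against 641 and 528 for independent lists, 0 and 0 for simulated unchanged groups, and medians of 1228 and 1187 with the captured arrays split between the comparisons. Opposite calls numbered 380, against 1229 for independent lists. Across genes, which are not independent replicates, the 2 log2 differences correlated at 0.578, with a covariance of 1.86. With the captured arrays split between the comparisons, the median correlation was 0.556 (0.522 to 0.579). The median covariance was then 1.81 (1.73 to 1.86). Simulated unchanged groups with shared arrays gave a correlation of 0.502 and a covariance of 0.0485. The 2 differences had the same sign in 66.8% of genes, against 66.7% in the simulated groups, and this share was not counted with split arrays. The simulated groups hold no effect, so their correlation and share of signs do not measure what sharing adds here. Treat left 640 genes higher and 624 lower in both groups. The balance turned to 1238 higher and 1372 lower with arrays centred on the median, and to 671 and 1295 with the 3 prime minus 5 prime gap as a covariate. It also turned with no low-value filter, quantile normalization, the probe of the highest captured mean, and without the x_at and s_at probe sets or 5 captured arrays.

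Sorted cells were also set against both references at once. Immediate early genes were higher in sorted cells than in both references in 19 of 28 members, NF-kappaB targets in 12 of 15, chemokines in 5 of 8, cytokines in 8 of 19, the unfolded protein response in 8 of 14 and heat shock proteins in 6 of 13. HSPA6 was at 14.17 ± 0.36 in sorted cells, 7.60 ± 0.41 in captured epidermis and 4.30 ± 0.87 in cultured cells, and ATF3, a stress-induced transcription factor, at 13.86 ± 0.48, 7.38 ± 0.94 and 7.84 ± 1.56. Cell cycle genes were lower in sorted cells than in both references in 17 of 23, with TOP2A, a topoisomerase of dividing cells, at 4.28 ± 1.78, 8.59 ± 0.82 and 9.86 ± 2.30. Over all genes 841 were higher and 1389 lower than both references, against 349 and 843 for independent lists and 0 for simulated unchanged groups, and the 2 comparisons share the sorted arrays. Independent lists ignore that sharing and the sorted arrays were not split, so the excess over them has no proper reference. Unchanged groups give almost no calls, so their 0 was fixed in advance, here and above. With arrays centred on the median the balance turned, to 1173 higher and 981 lower. Treat left 429 and 498, and averaging all probes of a gene left 836 lower.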

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

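The tests of the lost 5 prime signal, T cells and myeloid cells on the stress genes and the hair follicle test were chosen after the result was seen; the split counts and the opposing-probe test were written before. The first pattern is the rise of immediate early, NF-kappaB and chemokine genes in sorted cells. With the mean 3 prime minus 5 prime gap as a covariate, the 51 tested members of the 3 lists were 2.996 log2 units higher than in captured epidermis by the median (quartiles 1.998 and 5.29, with 43 called higher), against 3.50 without it (quartiles 2.05 and 5.44, with 44 called higher). The ACTB gap was at least 8.45 on captured arrays and at most 6.29 on the others. The covariate thus extends slopes within groups beyond their range and cannot decide on lost 5 prime signal, which stays open. Of 15 T cell and pan-leukocyte markers 5 were at least 1 log2 unit above their captured mean in sorted cells, among them IL7R, TRBC1 and LCK at means of 8.37, 5.83 and 5.48, against 2.99, 2.42 and 2.41 in captured and 5.23, 2.39 and 2.29 in cultured samples. PTPRC, carried by all leukocytes, was not called higher (5.81 ± 2.86 against 5.23 ± 0.63). The Langerhans cells of captured epidermis carry it too, and their markers fell in sorted cells. Its mean therefore does not count T cells. Between the 5 sorted arrays with the highest and the 5 with the lowest mean over these markers PTPRC was at 8.09 and 3.53, but the members differed by a median of -0.17 (quartiles -0.41 and 0.04), which argues against T cells as the whole cause but not as a part of it, and the sort gate is not given. Myeloid cells and, untested, a response to dissociation, which the design names, stay open. Of 11 myeloid markers only 1, ITGAM, was at least 1 log2 unit above its captured mean in sorted cells (5.10 against 3.33). TYROBP and CSF1R, at 5.07 and 4.60 in captured epidermis, were at 2.28 and 2.40 in sorted cells. That argues against a gain of cells carrying TYROBP or CSF1R. Between the sorted arrays with the highest and lowest mean over the 11 markers the members differed by a median of 0.24 (quartiles 0.03 and 0.44). ITGAM was at 6.11 and 4.09 on these arrays. The markers thus move apart and do not measure 1 share.

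The second pattern is 297 genes of 4835 with several detected probes, of which 1 probe rose and another fell at least 2-fold between sorted cells and captured epidermis. Across the 10 captured arrays, the mean difference between such probes followed the mean ACTB and GAPDH 3 prime minus 5 prime gap (Pearson r = 0.930, permutation p = 0.000180; Spearman rho = 0.952, p = 0.000110; 2 relations, both adjusted p = 0.000180, two-sided; r = 0.868 without the 2 arrays farthest from the median gap). Weaker signal from the 5 prime end on the captured arrays, from RNA integrity or amplification, may therefore account for opposing probes. Biological differences in transcript ends were not tested.

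The third pattern is the signal of keratin-associated protein genes in sorted cells, with KRTAP3-2 at 11.39 ± 1.57 and KRTAP19-1, named after its value was seen, at 9.85 ± 0.88. Hair follicle cells stay open: of a list of 47 hair follicle genes, 11 were tested, and 6 of them were higher and 4 lower in sorted cells than in captured epidermis. The higher ones included all 4 tested genes of the outer root sheath and bulge, and 2 of 7 tested genes of the hair shaft and inner root sheath. The 35 shaft and inner root sheath genes on the array, a part split off after its levels were seen, had a median level of 2.34 in sorted cells (quartiles 2.26 and 2.85), with KRT35 and KRTAP3-1 at 2.26 and KRT85 at 2.69, but these 3 genes were near the floor in all 3 groups, so the levels decide nothing about hair shaft cells. Apart from hair follicle cells no explanation was tested, neither other transcripts read by the probes nor a biological one.

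Of 100 splits drawn for each comparison, the real one included, only the real split reached its own count (1 of 100 each time). The groups lay apart on the principal components, so mixed splits were bound to give fewer calls. The splits also cannot separate group from batch, donor or preparation. The real counts, from the 2 groups compared alone, and the highest of the other splits were 4939 and 2191 for sorted against captured samples, 5257 and 2 for cultured against captured, and 5023 and 2535 for sorted against cultured. For genes called the same way in sorted and cultured against captured samples they were 2583 and 0, and in sorted cells against both references 2230 and 0.

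An array far from the others of its group was found in 52 of 357 groups of 10 values examined, for 115 genes and 4 array controls, where chance gives about 1 in 20. The array with the most was cultured replicate 5, with 18. Its values, with the range of the other 9 arrays in brackets, were lower for AURKA at 6.33 (10.07 to 11.84), BUB1B at 3.83 (8.87 to 10.78), CCNB1 at 7.16 (10.94 to 12.17), FDPS at 11.54 (13.14 to 14.51), FN1 at 11.44 (12.90 to 14.29), FOS at 3.43 (5.61 to 7.89) and ISG15 at 6.48 (9.18 to 12.15). They were also lower for MFAP5 at 8.36 (9.61 to 10.89), RRM2 at 8.01 (11.34 to 12.81), SPINK6 at 6.04 (9.87 to 13.31), SQLE at 11.45 (12.28 to 13.07), TOP2A at 3.47 (9.74 to 11.35), TPX2 at 4.42 (8.53 to 9.84) and TYMS at 8.58 (10.92 to 12.68). They were higher for DBP at 4.02 (2.75 to 3.06), MMP3 at 10.25 (2.53 to 3.90), PPP1R15A at 9.97 (5.98 to 7.99) and TSLP at 9.04 (4 to 6.03).

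The other arrays that stood apart are given with the range of the remaining 9 in brackets. On sorted arrays the lowest array stood apart for ATF3 at 12.73 (13.58 to 14.46), CD200 at 4.94 (7.35 to 10), HLA-B at 12.35 (13.11 to 13.75), IL1RL1 at 12.78 (13.63 to 14.43), KRT1 at 11.37 (12.84 to 14.25), KRT10 at 14.16 (14.98 to 15.49), NFKBIZ at 12.26 (13.51 to 14.46), S100A7 at 8.20 (11.84 to 14.16) and S100A8 at 11.56 (13.49 to 14.87). On the same arrays the highest array stood apart for IL37 at 4.55 (3.98 to 4.11). On cultured arrays the lowest array stood apart for DKK1 at 10.09 (11.58 to 12.23). On the same arrays the highest array stood apart for HSPA6 at 6.42 (3.67 to 4.92), IRF1 at 6 (4.75 to 5.36) and NLRC5 at 6.34 (2.26 to 4.40). On captured arrays the lowest array stood apart for HLF at 5.09 (7.58 to 9.09) and TYMS at 7.76 (8.71 to 9.65). On the same arrays the highest array stood apart for GATM at 12.72 (11 to 11.47) and S100A9 at 8.85 (3.28 to 5.93). Where the other 9 arrays all lay below 4 log2 units, the arrays apart were those of AZGP1, sorted, at 6.51 (2.83 to 3.94), CCL27, cultured, at 3.14 (3.06 to 3.07), CXCL2, captured, at 2.26 (2.59 to 2.62), CXCL3, captured, at 3 (3.45 to 3.53), CXCL8, captured, at 3.47 (2.26 to 2.74), HLA-DQB2, sorted, at 3.09 (2.29 to 2.54), HLA-DQB2, cultured, at 2.42 (2.27 to 2.29), IL1RL1, captured, at 2.32 (2.48 to 2.58), KRTAP19-1, captured, at 2.52 (2.27 to 2.31), KRTAP19-1, cultured, at 4.65 (2.27 to 2.79), KRTAP3-2, captured, at 2.31 (2.26 to 2.26), MFAP5, captured, at 2.31 (2.26 to 2.28), NR4A2, captured, at 5.55 (2.48 to 3.87), SPINK6, captured, at 2.36 (2.26 to 2.31), STARD4, sorted, at 6.08 (2.31 to 3.61) and UPK1B, captured, at 4.39 (2.35 to 2.89).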

How the results depend on the processing

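The settings that leave out 5 captured arrays, use the 3 prime minus 5 prime gap as a covariate or take the probe with the highest captured mean, and the leave-one-out of the control gaps, were chosen after the data were seen; the others were set before the data were examined. The number of arrays and the signal over the floor limit the precision. The counts of genes stayed within 1.5 times under the filters, scalings, probe rules, moderation, weights, 2-group fits and the 5 arrays left out, except the values given here. Treat, by its construction stricter, gave 1313 higher and 1494 lower for sorted against captured, 1855 and 1206 for cultured against captured, 958 and 1870 for sorted against cultured, 640 above and 624 below captured in both, and 429 above and 498 below both references. Probe means gave 836 below both references. The gap covariate gave 1390 higher in cultured than captured samples, 671 above captured in both, and CCL20 1.60 higher in culture (adjusted p = 0.224, limma with Benjamini-Hochberg; 1.90e-06 to 0.0108 over its other settings); the cause was not tested. Shifted lists in the 3 comparisons numbered 15, 13 and 14 in the main setting, 4, 2 and 3 with an estimated correlation, 25, 31 and 26 by fry for 1 direction and 30, 31 and 30 by fry for either, tests that do not compare a list with other genes. With no low-value filter 20 lists shifted in cultured against captured samples.

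Results of named genes other than CCL20 were counted per gene and comparison. Calls ended for 0 of 130 with probe means, 0 of 104 that kept a probe without the x_at and s_at probe sets, 0 of 132 with centred arrays, 0 of 132 by treat, 0 of 128 without 5 captured arrays, 3 of 132 with the gap covariate and 1 of 132 with the probe of the highest captured mean. They ended for none with the filters, quantile normalization, trend, weights, 2 groups or block. CCL20 in cultured against captured samples also lost its call with the gap covariate, as given above. Most of these genes were chosen for large called changes in the same data, so few calls could end, here or with 1 array left out. A direction turned for oxidative phosphorylation (cultured against captured) at -0.76 with the gap covariate (camera adjusted p = 0.0117, range 0.0117 to 0.945 over its settings), against 0.49 in the main setting; the cause was not tested. Leaving out each array in turn kept CCL20 between 10.91 and 11.08 in sorted against captured samples, between 1.98 and 2.59 in cultured against captured and between 8.41 and 9.02 in sorted against cultured, and ended 0 of 3920 gene calls and 34 of 3030 list results, with 36 gained. The low-value filter was applied again each time, so some genes left the test. The changed list results therefore do not show the weight of single arrays alone. The replicate numbers showed no strong pairing of the samples: 0, 3 and 2 of 10 samples correlated best with their own number in the 3 comparisons. The median correlation with the own number was 2e-04, 0.050 and 0.056, against -6e-04, -0.016 and 0.007 for other pairs. Shared donors or processing runs therefore cannot be excluded. With the number as a block, 2186 genes were higher and 2775 lower in sorted against captured samples, 3186 and 2068 in cultured against captured and 1730 and 3305 in sorted against cultured.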

Other observations

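The hair follicle genes and the settings with the gap covariate were chosen after the data were seen, and the lists were fixed before the data were examined. Clock genes differed between cultured cells and both other groups. In cultured cells 10 of 14 circadian clock genes fell and 1 rose against captured epidermis, with HLF (log2 difference -5.71), PER2 (-4.30) and DBP (-3.44), at camera adjusted p = 0.00185 (adjusted p = 0.167 with an estimated correlation). Sorted cells were higher than cultured cells in 11 and lower in 1, with BHLHE41 (3.69) and CIART (3.61), at camera adjusted p = 4.38e-05 (adjusted p = 0.0592 with an estimated correlation). Against captured epidermis, 5 of 14 clock genes were higher in sorted cells, BHLHE41 and CIART among them. Another 5 were lower, or 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.808). Barrier lipid genes fell in 7 of 11 in culture, with the lipoxygenase ALOX12B (-2.90), at camera adjusted p = 0.0143 (adjusted p = 0.577 with an estimated correlation). Sorted cells exceeded cultured cells in 7 of 11, with the fatty acid elongase ELOVL4 (2.40), at camera adjusted p = 0.00299 (adjusted p = 0.435 with an estimated correlation). MHC class I genes fell in 5 of 14 in culture, with their regulator NLRC5 (-6.34) and HLA-B (-2.41), at camera adjusted p = 0.00763 (adjusted p = 0.424 with an estimated correlation). They were higher in 6 and lower in 1 of 14 in sorted than in cultured cells (camera adjusted p = 0.00411, adjusted p = 0.375 with an estimated correlation). Melanocyte markers fell in 8 of 10 in culture (camera adjusted p = 0.00763, adjusted p = 0.555 with an estimated correlation). They were higher in sorted than in cultured cells in 10 of 10 (camera adjusted p = 0.00155, adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone the other counts in this paragraph were the same. With the 3 prime minus 5 prime gap as a covariate the clock list of cultured against captured samples did not pass (camera adjusted p = 0.277, range 0.000333 to 0.277 over its settings). Without the x_at and s_at probe sets the class I list did not pass in cultured against captured samples (0.0701, range 0.00147 to 0.424 over its settings) or sorted against cultured samples (0.100, range 0.00147 to 0.375 over its settings), where its median turned from 0.78 to -0.13. Nor did the melanocyte list in cultured against captured samples (0.0559, range 0.000642 to 0.555 over its settings). With a stricter filter the barrier list in the same comparison had camera adjusted p = 0.0502, range 0.00202 to 0.577 over its settings.

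Interferon-stimulated genes rose in 11 of 15 members in cultured cells and fell in 1, with ISG15 at 4.49, although the list did not pass in the main setting (camera adjusted p = 0.0821). It passed with no low-value filter, quantile normalization, centred arrays or array weights (camera adjusted p = 0.00150 to 0.0417, range 0.00150 to 0.708 over its settings), and without captured replicate 7 (0.0407) or cultured replicate 5 (0.0190). In sorted against captured samples it rose in 6 of 15, or 5 adjusted over the list alone, and fell in 0 (camera adjusted p = 0.0558), and passed with no low-value filter, quantile normalization, array weights, 2-group fits, the replicate block, 5 captured arrays left out or the probe highest in captured epidermis (camera adjusted p = 0.0250 to 0.0473, range 0.0241 to 0.704 over its settings). The prostaglandin enzyme PTGS2 was at 5.84 ± 1.06 in captured, 9.30 ± 0.77 in sorted and 12.51 ± 1.38 in cultured samples, and its relative PTGS1 at 11.91 ± 0.40, 9.24 ± 1.15 and 6.38 ± 1.54. The prostaglandin list rose in 5 and fell in 2 of 8 in culture (camera adjusted p = 0.697). Sweat gland and appendage markers rose in 6 of 9 and fell in 1 in sorted cells, with SOX9 (7.25) and KRT77 (-4.83), at camera adjusted p = 0.0482 (adjusted p = 0.435 with an estimated correlation). This call was lost with no low-value filter, a stricter one, centred arrays, probe means, the gap covariate or without the x_at and s_at probe sets (range 0.0234 to 0.435 over its settings). It was also lost without any 1 of captured replicates 1, 2, 3, 4, 7, 8, 9 or 10 (0.0510 to 0.0607) or sorted replicates 1, 3, 4, 5, 6, 7, 8 or 9 (0.0580 to 0.0990). Without an array, members could leave this list through the filter, so these losses do not show dependence on single replicates. SOX9 is a transcription factor of the hair follicle and sweat gland. Outer root sheath and bulge genes of the hair follicle, chosen after values were seen, were at 8.26 ± 1.49 for CD200 and 6.60 ± 3.47 for LHX2 in sorted cells (SD, n = 10), against means of 2.79 and 2.27 in captured epidermis.

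The remaining lists did not pass in any comparison in the main setting. The counts called higher and lower, in sorted against captured, cultured against captured and sorted against cultured samples are given in turn. They were 6 and 5, 6 and 4 and 3 and 2 of 14 pattern recognition genes. The next were 2 and 0, 4 and 0 and 1 and 3 of 8 T cell contact genes, and 0 and 1, 3 and 0 and 0 and 5 of 20 oxidative phosphorylation genes. For structural genes they were 0 and 0, 0 and 0 and 0 and 0 of 17 ribosomal protein genes, and 6 and 6, 6 and 5 and 3 and 4 of 20 junction genes. For markers of other cell types they were 2 and 4, 3 and 4 and 3 and 4 of 10 fibroblast and dermal matrix markers, 1 and 0, 2 and 0 and 0 and 1 of 2 endothelial and pericyte markers, and 1 and 0, 1 and 1 and 2 and 0 of 3 T cell and pan-leukocyte markers. The last were 1 and 0, 0 and 0 and 1 and 0 of 1 myeloid markers, and 0 and 0, 1 and 0 and 0 and 1 of 1 Merkel cell and nerve markers. The smallest camera adjusted p among these lists was 0.0546 in that setting. Adjusted over the list alone they were the same, except that pattern recognition genes called lower in sorted than in cultured cells numbered 1. No erythrocyte marker passed the low-value filter. The median, the mean and the camera direction differed in sign in 7, 4 and 8 lists in the 3 comparisons, none of which passed. For sorted against captured samples these were basal keratinocyte, barrier lipid synthesis, antigen presentation MHC class I, prostaglandin synthesis and receptors, circadian clock, melanocyte markers, Merkel and nerve markers. For cultured against captured samples they were cytokines, pattern recognition and inflammasome, adherens junction and desmosome, fibroblast and dermal matrix markers. For sorted against cultured samples they were cornified envelope and granular layer, wound and migration keratins and proteases, NRF2 oxidative stress targets, interferon-stimulated genes, pattern recognition and inflammasome, glycolysis and hypoxia, adherens junction and desmosome, fibroblast and dermal matrix markers.

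Several lists below the threshold in the main setting passed in others. The oxidative phosphorylation list passed in sorted against cultured samples with no low-value filter, quantile normalization or 2-group fits (camera adjusted p = 0.00118 to 0.0486, range 0.00118 to 0.776 over its settings), at medians of -0.68 to -0.64. It also passed there without sorted replicate 7 or 9 (0.0341 to 0.0493) or cultured replicate 7 (0.0464). With the gap covariate it was lower in sorted than in captured samples (median -1.14, camera adjusted p = 0.000347, range 0.000347 to 0.981 over its settings). In cultured against captured samples its direction turned with that covariate, from a median of 0.49 to -0.76 (camera adjusted p = 0.0117, range 0.0117 to 0.945 over its settings), while it passed upward with no low-value filter (0.0442). The ribosomal list was lower in cultured than in captured samples with no low-value filter, centred arrays, probe means, trended and robust moderation, array weights, 5 captured arrays left out or the gap covariate (camera adjusted p = 0.00432 to 0.0356, range 0.00432 to 0.708 over its settings), at medians of -0.60 to -0.26. It also passed there without captured replicate 5, 7 or 9 (0.0354 to 0.0447) or cultured replicate 1 (0.0499). With centred arrays it was higher in sorted than in cultured samples (median 0.46, camera adjusted p = 0.00461, range 0.00461 to 0.823 over its settings). The T cell and pan-leukocyte list was below the threshold in sorted against captured and against cultured samples in the main setting (camera adjusted p = 0.423 and 0.117) and passed by camera only with no low-value filter, higher in sorted cells (camera adjusted p = 0.0160, range 0.0160 to 0.704 over its settings, and 0.000741, range 0.000741 to 0.435 over its settings). With no low-value filter the myeloid list was lower in cultured than in captured samples (0.0485, range 0.0485 to 0.949 over its settings).

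In cultured against captured samples, heat shock proteins (7 higher and 1 lower of 13, camera adjusted p = 0.0546 in the main setting) passed with no low-value filter, a stricter filter, centred arrays, probe means, trended and robust moderation, array weights or the probe highest in captured epidermis (camera adjusted p = 0.00225 to 0.0455, range 0.00225 to 0.701 over its settings). Glycolysis and hypoxia genes (13 higher and 2 lower of 18, camera adjusted p = 0.0612 in the main setting) passed with no low-value filter, centred arrays, probe means, the x_at and s_at probe sets left out, array weights or the probe highest in captured epidermis (camera adjusted p = 0.00358 to 0.0450, range 0.00358 to 0.720 over its settings). NRF2 targets (7 higher and 1 lower of 11, camera adjusted p = 0.0546 in the main setting) passed with no low-value filter, quantile normalization, centred arrays, probe means or the probe highest in captured epidermis (camera adjusted p = 0.00474 to 0.0495, range 0.00474 to 0.435 over its settings). Sweat gland and appendage markers (6 higher and 1 lower of 9, camera adjusted p = 0.0546 in the main setting) passed with a stricter filter, quantile normalization, centred arrays, array weights, 5 captured arrays left out or the gap covariate (camera adjusted p = 0.00752 to 0.0416, range 0.00752 to 0.981 over its settings). All of these lists had positive medians, from 1.03 for heat shock proteins to 5.56 for sweat gland markers. Without 1 array, heat shock proteins also passed for 5 of the cultured, 1 of the captured and 1 of the sorted arrays. NRF2 targets passed for 4 of the cultured arrays and 1 of the captured ones. Sweat gland markers passed for 8 of the sorted, 1 of the captured and 1 of the cultured arrays. Leaving out sorted replicate 1 leaves the cultured and captured values unchanged, yet moved their median from 4.84 to 5.27. Members had thus left this list through the low-value filter, which was applied again.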
